A study of Homo sapiens with 3 samples.

How the data were processed

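RNA of HT-29 cells was measured on 3 two-colour Agilent arrays of 1 slide, scanned in 1 scan. Per the labels' protocols, cells attached for 24 h, were treated for 48 h with the extract or with vehicle (0.1% DMSO), and were lysed in Trizol, and 300 ng of total RNA was labelled for each channel. Every array carried extract-treated RNA in Cy3 and vehicle RNA in Cy5. The labels call the 3 arrays biological replicates, and the culture of vehicle cells used on each array is not given in the sources used here. The comparison has 1 group of 3 arrays, tested against a ratio of no change.

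The scanner files hold intensity values per spot, written by Feature Extraction 10.7.3.1 per the file headers, as mean signal, local background and a processed signal that the software had corrected for background and for dye. They also hold a log10 ratio of red over green, computed by the same software per the file headers. The authors' deposited value table holds log2 ratios, and the submitters' processing notes name limma with no further detail. Set against the ratios computed here, its 3 columns correlated at 0.977, 0.988 and 0.984 across genes with slopes of 1.12, 0.996 and 0.881, which gives a log2 scale and the direction of extract over vehicle. The column medians were -0.00313, 0.00066 and -0.00571, so each column was centred, and the background correction and filter behind the table stay unknown.

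Mean signals and background medians were corrected with normexp at an offset of 50 and normalized within each array by loess, with control spots at weight 0 (limma 3.58.1, R 4.3.3). The offset draws ratios of dim probes toward 0. Spots with outlier flags (604, 688 and 630 on the 3 arrays) were left out, and no spot was saturated. Of 62976 spots 4259 were controls, and none of 137 control probes other than grid landmarks was well above background in both channels on all arrays. Spots of 1 probe were averaged. Probes were kept if at least 50% of their spots, in at least 1 channel, were well above background on all 3 arrays, which left 15417 of 42405 probes, and the brightest probe stood for its gene. Of 1979 genes with another kept probe at a separate place, 1297 had the same sign in both, with a correlation of 0.436 across genes. Of 496 changed genes with any other kept probe, 381 had 1 sign in all of them. Of the 12790 genes tested, 9653 were well above background in both channels, 3120 only in the red channel and 17 only in the green channel on all arrays. Red always carried vehicle RNA, so dye and sample are not separated in these numbers. Of 42405 probes 31628 were matched to current symbols of the GRCh38.p14 gene table by symbol, accession or synonym, and 1114 tested features have no gene name. Coordinates are those of the array files (hg19).

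Log2 ratios were tested against 0 with lmFit and eBayes, with 2 residual and 16.6 moderated degrees of freedom, and adjusted by Benjamini-Hochberg at 0.05. A set of 42 gene lists was fixed before the data were examined, and the 39 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, a rotation test, stood beside it, and neither passed any list. With an estimated correlation camera uses the 2 residual degrees of freedom, so few lists can pass. Named genes were chosen by a rule fixed before the data were examined. It took the 10 largest rises and falls among genes past the threshold, of 1 sign on all arrays and well above background in both channels. It also took up to 2 genes per direction that were dark in 1 channel, up to 3 members of each list that passed, and 2 members of other lists with at least 3 changed members. Some genes that this rule takes are not reported here. For genes dark in the extract channel the fold is a bound against the lowest signal of probes well above background, per channel after loess and Aquantile, and is open to dye bias.

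On simulated ratios for 12790 genes, the test of extract against vehicle recovered 77.6% of changes of 0.5, 100% of changes of 1 and 100% of changes of 2 on the log2 scale, with 15 false calls. In a simulation with 1 list moved by 0.4, camera called that list and no other. The moved list had an adjusted p of 0.124 with the estimated correlation and 0.0519 with fry, so neither called it. Failure of a list under either of these tests therefore does not show that the list was unmoved. The simulated genes varied independently, which real genes do not.

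Alternatives fixed before the data were examined were no background subtraction, the scanner's processed signals, median centring, Aquantile, an offset of 10, other filters, the mean of probes, the authors' value table, trend and robust moderation, a separate-channel model (statmod 1.5.0), kept outlier spots, each array left out, and a test against 1.5-fold. For the trend and separate-channel fits the list test ran on their statistics (cameraPR). Processed signals with trend and robust moderation, and median centring over the genes tested, were added after the data were seen.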

Results

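HT-29 cells, an established line from a human colon adenocarcinoma, were treated for 48 h with an extract of banana passion fruit (Passiflora mollissima) seeds made by pressurized liquid extraction, or with its vehicle, 0.1% DMSO. The extract was given at the concentration that had inhibited the cells by 50% in a proliferation assay, and the question was which transcripts accompany that anti-proliferative effect. RNA of treated and vehicle cultures was hybridised to 3 two-colour arrays with 62976 spots each, labelled as 3 biological replicates. On each array the extract-treated RNA carried Cy3 (green) and the vehicle RNA carried Cy5 (red), with no exchange of dyes. A dye effect of a single probe therefore enters every ratio below together with the effect of the extract. Ratios are log2 values of extract over vehicle, given as mean ± SD over the 3 arrays (n = 3), and the small number of arrays limits their precision. Between 27.1% and 42.4% of probes were well above background in the green channel and between 36.9% and 49.1% in the red channel, and array 1 had the lowest share in both.

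Many transcripts differed by small amounts between extract and vehicle. Of 12790 genes tested, 2493 passed an adjusted p of 0.05 (limma), 897 of them higher and 1596 lower with the extract. The median absolute log2 change of these genes was 0.406, and 23 changed at least 2-fold, 10 upward and 13 downward. The largest rise among the genes that could be named was that of ITGB7, an integrin beta chain (1.58 ± 0.301, 2.99-fold, adjusted p = 8.31e-07). The largest fall was that of ANXA13, an annexin of the intestinal epithelium, which fell by 2.32 ± 0.54 on the log2 scale (adjusted p = 1.2e-07). In the coordinates of the array files (hg19) the ITGB7 probe lies on chromosome 12 from 53585157 to 53585216 and the ANXA13 probe on chromosome 8 from 124693388 to 124693447.

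The other large rises, among genes well above background in both channels on all arrays, were smaller. DEFB1, an epithelial defensin, rose by 1.14 ± 0.224 and SLPI, a secreted protease inhibitor, by 1.03 ± 0.281. ADAMTS13, the protease that cleaves von Willebrand factor, rose by 1.12 ± 0.224, UPK3B by 1.07 ± 0.231 and IGFBP6 by 1.02 ± 0.146. COTL1 (0.985 ± 0.166), KPNA2, an importin (0.982 ± 0.205), and SERPINA3 (0.962 ± 0.37) rose slightly less. The large falls held 4 members of the list of ATF4 targets, CHAC1 (-1.4 ± 0.344), DDIT4 (-1.35 ± 0.173), TRIB3 (-1.33 ± 0.502) and ATF3 (-1.09 ± 0.132). Other kept probes read less, with a median of -0.286 for CHAC1 and -0.196 for ATF3, and with the mean of probes these genes were at -0.845 and -0.495. The others were TMEM65 (-1.46 ± 0.606), APP (-1.23 ± 0.855), TTR (-1.16 ± 0.353), LGALS2 (-1.16 ± 0.362) and IHH, a hedgehog ligand (-1.14 ± 0.271). APP varied most, with ratios of -2.01, -0.313 and -1.37 on the 3 arrays, and did not pass with trend and robust moderation (adjusted p = 0.178). With the mean of probes APP was at -0.768 and SERPINA3 at 0.634. Among genes not well above background in the extract channel on any array, the bound on the fall with loess was 1.26-fold for ARHGEF15 and 1.24-fold for UBE2DNL. Both were chosen as dark in that channel, so their direction cannot be told apart from that choice and the dye. Of the named changed genes 10 were dark in the extract channel in this way and 0 in the vehicle channel. The log2 ratio of ARHGEF15 was -0.354, -0.518 with no background subtraction and -1.07 with the scanner's processed signals. That of UBE2DNL was -0.37, -0.576 and -0.604 in the same order. The direction of both reversed with median centring over the genes tested. ARHGEF15 did not pass in the authors' value table (adjusted p = 0.0611), UBE2DNL did not pass without array 2 (0.144), and neither passed without array 3 (0.321 and 0.322).

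**Figure D1:**
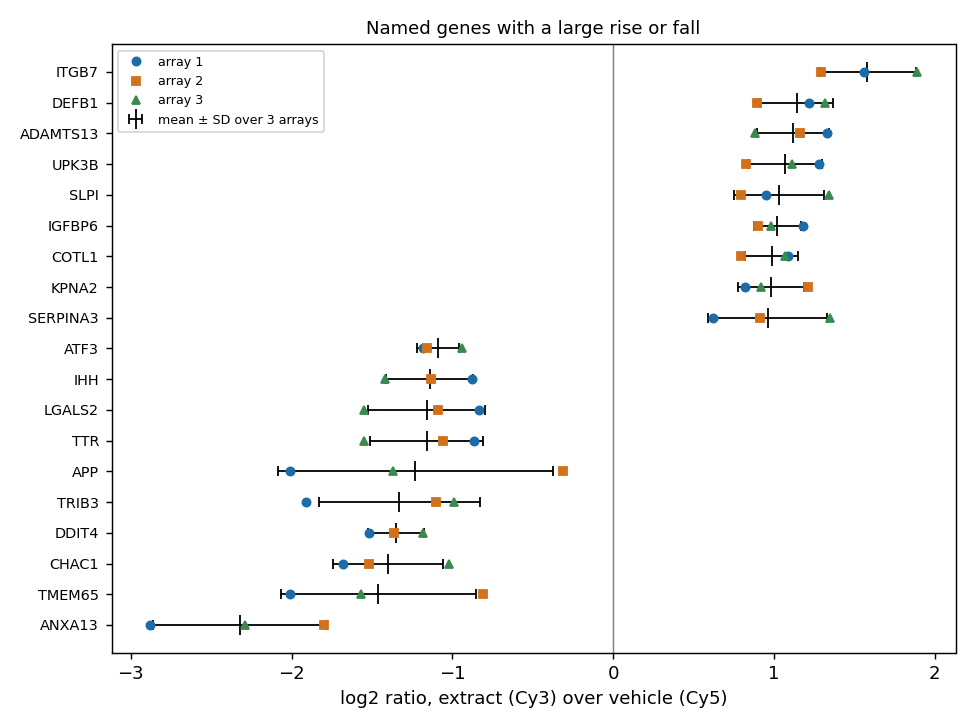
Log2 ratio of extract over vehicle (x axis) of the genes named above for a large rise or a large fall (y axis), with a point for each of the 3 arrays and a bar for the mean ± SD. These genes were chosen among those of 1 sign on all arrays. The means run from -2.32 for ANXA13 to 1.58 for ITGB7, and the points of APP are spread most widely.

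The number of changed genes rested on the processing and on the arrays used. It was 596 without array 3, 3 with the scanner's own processed signals, 7 in a test against a change of 1.5-fold, and 9709, of which 99.8% were lower, with median centring in place of loess. The share of lower genes was 64% with loess, 54.2% with median centring over the genes tested and 60.4% among genes well above background in both channels. Of the 3120 genes well above background on all 3 arrays in the vehicle (red) channel alone, 30 were higher and 291 lower (90.7%). In the extract channel these genes were well above background on fewer than 3 arrays, not necessarily on none. They passed the filter through the vehicle channel alone, so their share of lower calls cannot be told apart from the filter and the dye.

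Genes of the cell division cycle were higher with the extract. Of 36 tested genes of DNA replication and S phase 26 rose and none fell, with a mean log2 ratio of 0.38 ± 0.0342. MCM7 (0.746 ± 0.185) and MCM2 (0.663 ± 0.268), subunits of the replicative helicase, and GINS2 (0.67 ± 0.189), part of the same machinery, rose most. The other kept probe of MCM7 read 0.144, and with the mean of probes MCM7 was at 0.445, below the others. Of 35 mitosis genes 23 rose and none fell (mean 0.414 ± 0.217), led by the spindle checkpoint genes MAD2L1 (0.888 ± 0.046) and BUB1B (0.802 ± 0.422) and by the mitotic kinase CDK1 (0.765 ± 0.255). Adjusted over the list alone, 27 replication genes and 28 mitosis genes rose. Both lists had an adjusted p of 5.88e-17 with camera at its preset correlation. With an estimated correlation the adjusted p was 0.372 for replication and 0.486 for mitosis, and neither list passed. That correlation was -0.00519 for replication, below the preset 0.01, and 0.272 for mitosis. The mean of the mitosis genes was 0.19 on array 1 against 0.623 and 0.43 on arrays 2 and 3.

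Histone genes went the other way. Of 35 replication-dependent histone genes 11 fell and 1 rose (mean -0.183 ± 0.0866, camera adjusted p = 0.00991). The adjusted p was 0.677 with an estimated correlation, and 0.218 at the preset correlation without array 3. Adjusted over the list alone, 14 fell and 2 rose. The largest falls were those of H4C5 (-0.57 ± 0.303), H4C1 (-0.532 ± 0.211) and H4C4 (-0.513 ± 0.243), whose near-identical sequences leave the separate genes uncertain. Of 13 cyclin-dependent kinase inhibitors and related genes 2 rose, CDKN2C (0.61 ± 0.138) and CDKN3, a phosphatase (0.499 ± 0.151), and 1 fell, without a shift of the list (camera adjusted p = 0.399).

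Targets of ATF4, the transcription factor of the integrated stress response, were lower. Of 17 tested targets 13 fell and none rose, with a mean log2 ratio of -0.697 ± 0.214. Adjusted over the list alone, 14 fell. CHAC1, DDIT4 and TRIB3 fell most. The camera adjusted p was 2.96e-11 at the preset correlation, and the adjusted p was 0.486 with an estimated correlation of 0.464. Of 14 genes of serine and amino acid supply 5 fell and none rose, among them SLC7A11, the cystine transporter (-0.976 ± 0.876), and PSPH, of serine synthesis (-0.824 ± 0.264). SLC7A11 did not pass with trend and robust moderation (adjusted p = 0.257) and was at -0.5 without array 1. That list did not pass (mean -0.298 ± 0.259, camera adjusted p = 0.0608), but it did after correction for the base counts and brightness of the probes (adjusted p = 0.0357). With an estimated correlation and without that correction, the adjusted p of the list was 0.762. Of 20 aminoacyl-tRNA synthetases 3 fell and 2 rose (camera adjusted p = 0.982), and MARS1 (-0.569 ± 0.4) and SARS1 (-0.51 ± 0.653) had the largest changes. The only other kept probe of MARS1 read 0.0368. SARS1 did not pass with trend and robust moderation (adjusted p = 0.266), with an offset of 10 (0.0792), with no filter on dim probes (0.0844) or without array 1 (0.349, at -0.135). The mean of the synthetases was -0.457 on array 1 and 0.133 and 0.0997 on arrays 2 and 3.

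Chaperones and folding enzymes of the endoplasmic reticulum were slightly higher, 6 of 23 rising and 1 falling (mean 0.121 ± 0.0348, camera adjusted p = 0.0064). The adjusted p was 0.486 with an estimated correlation, and the direction of the list relative to other genes reversed with median centring. SDF2L1 (0.735 ± 0.384), PDIA4 (0.49 ± 0.273) and SEC61B (0.43 ± 0.252), a subunit of the translocon, rose most. HERPUD1, named after its value was seen because it was the only member that fell, had a log2 ratio of -0.698.

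Immediate early genes and growth factor feedback genes were lower. Of 24 tested 12 fell and none rose (mean -0.305 ± 0.0348, camera adjusted p = 3.85e-05), and the adjusted p was 0.486 with an estimated correlation. The largest falls were those of EGR1 (-0.866 ± 0.152), of SPRY2, an inhibitor of receptor tyrosine kinase signalling (-0.692 ± 0.0769), and of AREG, a ligand of the EGF receptor (-0.691 ± 0.354). Of 18 p53 targets 6 fell and 2 rose (camera adjusted p = 0.469), and of 20 pro-apoptotic genes 2 fell and 2 rose (camera adjusted p = 0.639). BBC3 (-0.74 ± 0.0468) and the death receptor TNFRSF10B (-0.599 ± 0.0746) belong to both lists. Of 10 NF-kappa-B targets and chemokines 3 fell and none rose (camera adjusted p = 0.946), including NFKBIA (-0.479 ± 0.08) and CXCL1 (-0.47 ± 0.0881).

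Interferon response genes were higher, 13 of 28 rising and none falling (mean 0.268 ± 0.059, camera adjusted p = 3.29e-08), and the adjusted p was 0.486 with an estimated correlation. IFIT1 (0.729 ± 0.278), the immunoproteasome subunit PSMB9 (0.711 ± 0.207) and the ubiquitin-like modifier ISG15 (0.615 ± 0.15) rose most. Of 34 genes in the list of proteasome subunits 9 rose and none fell (mean 0.169 ± 0.114, camera adjusted p = 1.85e-05). The mean of this list was 0.04 on array 1 against 0.258 and 0.21 on arrays 2 and 3. The adjusted p was 0.486 with an estimated correlation, and the direction relative to other genes reversed with median centring. PSMC2 (0.622 ± 0.348), PSMD11 (0.525 ± 0.064) and PSMD8 (0.492 ± 0.208) led the list.

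Among genes of redox defence, 9 of 22 NRF2 targets rose and 2 fell (mean 0.152 ± 0.0197, camera adjusted p = 0.00159), and the adjusted p was 0.486 with an estimated correlation. AKR1C1 (0.526 ± 0.0416) and FTH1, the ferritin heavy chain (0.498 ± 0.0907), rose most. Another kept probe of AKR1C1, which has close paralogs, read -0.0226, and FTH1 was lower with median centring over the genes tested. The NRF2 list did not pass with median centring (adjusted p = 0.816). Of 18 glutathione genes 5 rose and none fell (mean 0.164 ± 0.0634, camera adjusted p = 0.00182), with MGST1 (0.548 ± 0.102), GSS (0.495 ± 0.0986) and GPX3 (0.464 ± 0.109) ahead. The adjusted p was 0.577 with an estimated correlation, and the direction relative to other genes reversed with median centring.

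The lists of glycolysis, the respiratory chain, and autophagy and the lysosome were slightly higher with loess. Those of the tricarboxylic acid cycle and fatty acid oxidation did not pass. Of 18 glycolysis genes 5 rose and 1 fell (mean 0.154 ± 0.0681, camera adjusted p = 0.00182, and adjusted p = 0.521 with an estimated correlation), with PGAM1 (0.473 ± 0.132), LDHA (0.378 ± 0.148) and PFKP (0.37 ± 0.103) changing most. Of 36 genes of the respiratory chain 6 rose and 1 fell (mean 0.0927 ± 0.0117, camera adjusted p = 0.00427, and adjusted p = 0.486 with an estimated correlation), among them ATP5MC3 (0.497 ± 0.219), NDUFB3 (0.42 ± 0.122) and ATP5MC1 (0.396 ± 0.201). The direction of both lists relative to other genes reversed with median centring, and the respiratory chain then passed as lower (shift -0.198, adjusted p = 0.0195, and 0.00816 centred over the genes tested), while glycolysis did not pass (adjusted p = 0.927 and 0.827). Of 33 genes of autophagy and the lysosome 9 rose and 2 fell (mean 0.076 ± 0.0603, camera adjusted p = 0.016, and adjusted p = 0.525 with an estimated correlation). The lysosomal enzymes CTSD (0.568 ± 0.273) and NEU1 (0.467 ± 0.0965) were among those that rose. The list did not pass without array 2 (adjusted p = 0.0639) or array 3 (0.121), with no filter on dim probes (0.0583), among genes well above background in both channels (0.0887), or with median centring (0.884, and 0.822 over the genes tested).

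Ribosomal protein genes were lower, 10 of 36 falling and none rising (mean -0.222 ± 0.0512, camera adjusted p = 0.000372, and adjusted p = 0.486 with an estimated correlation). RPS20 (-0.505 ± 0.145), RPL14 (-0.462 ± 0.312) and RPL37 (-0.434 ± 0.0152) fell most. The list did not pass in the authors' value table (adjusted p = 0.214) or with the scanner's processed signals (adjusted p = 0.454). Of 29 genes of ribosome biogenesis and MYC 3 fell and 1 rose (camera adjusted p = 0.399), with RRS1 at 0.5 ± 0.0783 and NPM1 at -0.476 ± 0.568.

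Markers of colon cell types moved in both directions without a shift of any list. Of 9 tested enterocyte markers 3 fell and 1 rose (camera adjusted p = 0.865). CEACAM6, well above background in the vehicle channel on 2 of 3 arrays, rose (1.13 ± 0.433) and CEACAM1 fell (-0.493 ± 0.175). The value of CEACAM6 was 1.65 with an offset of 10 and 2.46 with the scanner's processed signals. Of 11 markers of secretory cells 3 fell and 1 rose (camera adjusted p = 0.56), including TFF3, a goblet cell peptide (-0.709 ± 0.248), and REG4 (-0.499 ± 0.357), and 1 of the other probes of TFF3 had the opposite sign. Of 22 genes of epithelial junctions and keratins 5 fell and 3 rose (camera adjusted p = 0.865), with CLDN2 at -0.863 ± 0.0609 and KRT8 at 0.797 ± 0.206, and with 1 of the other KRT8 probes opposite in sign. Of 15 Wnt target genes 2 fell, CD44 (-0.855 ± 0.27) and DKK1 (-0.495 ± 0.0987), and 2 rose (camera adjusted p = 0.0816). None of 14 listed fibroblast and endothelial markers was measured above the filter, and of 14 leukocyte markers 4 were tested, of which 1 rose and 1 fell. Of 21 mesenchymal and invasion genes 4 were tested and none passed.

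The remaining lists did not pass. Of 16 genes of iron handling 5 rose and 2 fell (camera adjusted p = 0.221), TFRC, the transferrin receptor, by 0.759 ± 0.7 with a ratio of 0.00365 on array 1. Of 20 genes of cholesterol synthesis 2 fell, among them SQLE (-0.383 ± 0.235), and 1 rose (camera adjusted p = 0.957). Of 18 genes of sphingolipid metabolism 2 rose and 1 fell (camera adjusted p = 0.262), with SGMS1, well above background in the extract channel on 2 of 3 arrays, at -0.433 ± 0.0619 and DEGS1 at 0.367 ± 0.147. SGMS1 was at -0.627 with no background subtraction and -0.709 with an offset of 10, and with the scanner's processed signals SGMS1 was at -0.766 and DEGS1 at 0.736. Fewer than 3 members passed in the lists of the tricarboxylic acid cycle (camera adjusted p = 0.0519), anti-apoptotic genes (0.399), metallothioneins (0.444), polyamine metabolism (0.444), mitochondrial stress (0.444), glucuronidation and efflux (0.773), HIF1 targets (0.783), the heat shock response (0.783), AhR targets (0.865), fatty acid oxidation (0.918) and fatty acid synthesis (0.918). Camera compares a list with the other genes, whose median log2 ratio was -0.0562, so that some of these lists, such as the heat shock response with a mean of -0.018, had a mean below 0 and an upward direction in the test.

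Other named genes of these lists lost their call under single settings. With the mean of probes MARS1 (adjusted p = 0.0789), AKR1C1 (0.077), LDHA (0.116), NPM1 (0.262), CEACAM1 (0.0632) and CXCL1 (0.0942) did not pass, and TFF3 was at -0.436 and KRT8 at 0.355. TFRC (0.16) and NPM1 (0.216) did not pass with trend and robust moderation. With an offset of 10 and in the authors' value table SQLE (0.0716 and 0.0602), LDHA (0.0595 and 0.0814), PFKP (0.0605 and 0.0713), ATP5MC1 (0.0525 and 0.0589) and NPM1 (0.0621 and 0.0827) did not pass, nor did SEC61B (0.0568) and RPL37 (0.0973) in that table. Without array 1, SQLE (0.0524), ATP5MC1 (0.0507) and NPM1 (0.273) did not pass, and without array 2 LDHA (0.125). NPM1 did not pass with no filter on dim probes either (0.0743). With median centring in place of loess, 12 of the 82 named genes kept their direction but did not pass, and 25 reversed. Centred over the genes tested, 16 kept their direction but did not pass, and 3 reversed. With the scanner's processed signals none of the 82 named genes passed, and AKR1C1 (0.891), GPX3 (0.776), CDKN2C (0.988), REG4 (-0.824), NDUFB3 (0.279), RPL14 (-0.279) and RPL37 (-0.211) moved by over 1.5 times. Without array 3, 30 of 82 named genes did not pass, with adjusted p from 0.0511 to 0.339. Besides ARHGEF15 and UBE2DNL these were SEC61B, AKR1C1, FTH1, GSS, GPX3, PSMD11, PSMD8, SQLE, PGAM1, LDHA, PFKP, NDUFB3, ATP5MC1, CDKN3, NEU1, RRS1, NPM1, RPS20, RPL14, RPL37, H4C5, H4C1, H4C4, REG4, NFKBIA, CXCL1, SGMS1 and DEGS1.

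Adjusted over the list alone, 15 interferon response genes rose and 1 fell, 10 proteasome genes rose, 12 immediate early genes fell and 12 ribosomal protein genes fell. By the same measure 10 NRF2 targets rose and 2 fell, 6 glutathione genes rose, 6 glycolysis genes rose and 1 fell, and 6 genes of the respiratory chain rose and 1 fell. Of the chaperones of the endoplasmic reticulum 6 rose and 1 fell, of autophagy and lysosome genes 10 rose and 2 fell, of serine and amino acid supply 7 fell and 1 rose, and of p53 targets 7 fell and 3 rose, also adjusted over the list alone.

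**Figure D2:**
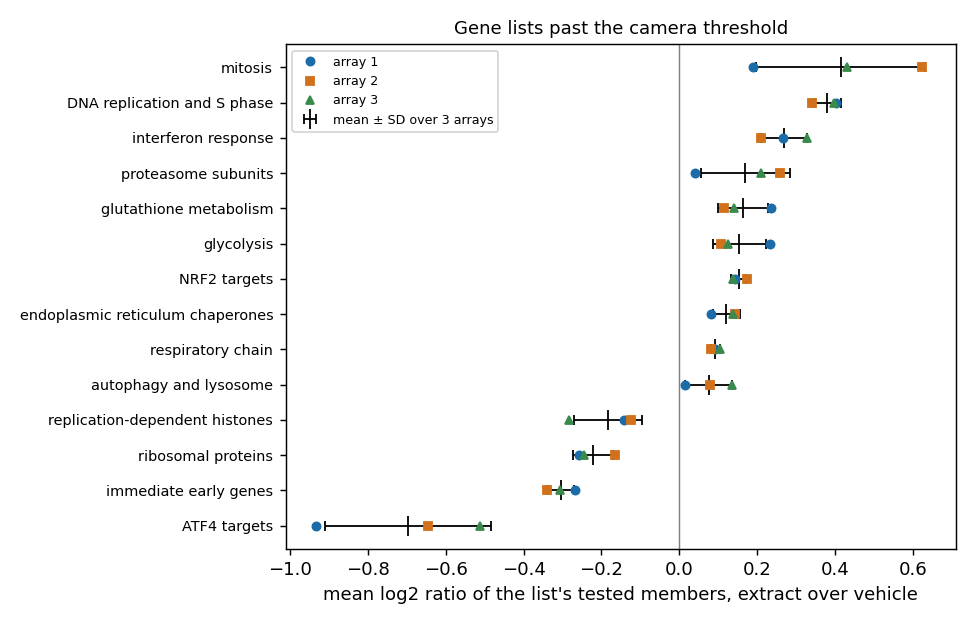
Mean log2 ratio of extract over vehicle of the tested members (x axis) of the 14 gene lists that passed camera at its preset correlation (y axis), with a point for each of the 3 arrays and a bar for the mean ± SD over arrays. The means run from -0.697 for ATF4 targets to 0.414 for mitosis genes, and array 1 has the lowest mean in both of these lists.

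The 3 arrays ran in the same direction to different degrees. Across 12790 genes, which are not independent replicates, the Pearson correlation of the log2 ratios was 0.379 between arrays 1 and 2, 0.581 between arrays 1 and 3 and 0.692 between arrays 2 and 3. The ratios had 1 sign on all arrays for 53.2% of the tested genes, where independent signs would give 25%. A dye effect of a probe would also repeat on all arrays, so this agreement does not separate the extract from the dye. With the scanner's processed signals the correlation of arrays 1 and 2 was 0.205, and with median centring in place of loess it was 0.692. Median centring leaves a trend with brightness in the ratios (median -0.268 for dim and -0.832 for bright genes). Such a trend can raise the correlation across genes.

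**Figure D3:**
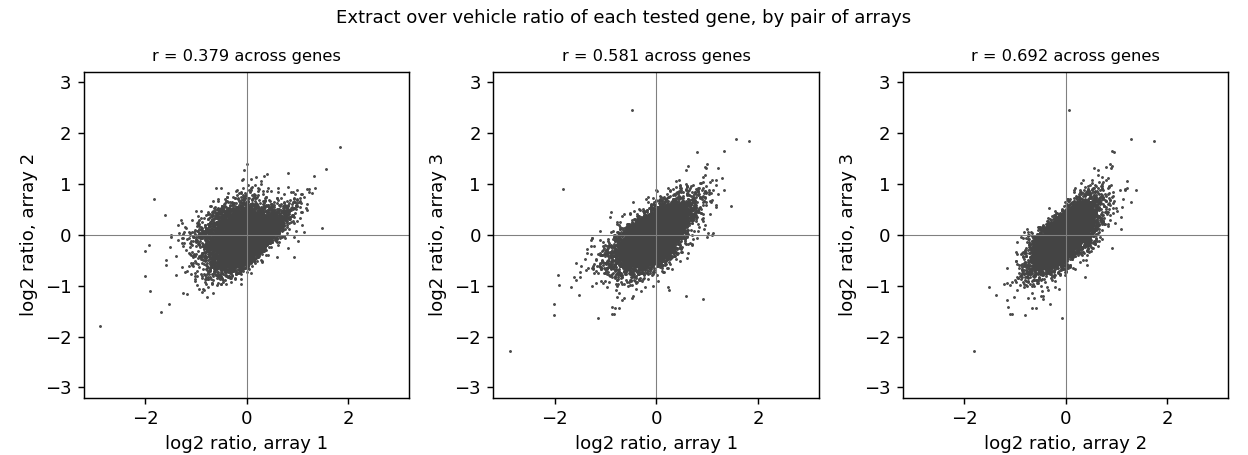
Log2 ratio of extract over vehicle of each of the 12790 tested genes on 1 array (x axis) against another (y axis), a panel for each pair of the 3 arrays. The points lie closest to a line for arrays 2 and 3 (r = 0.692) and are most scattered for arrays 1 and 2 (r = 0.379).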

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

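Processed signals with trend and robust moderation and median centring over the genes tested were chosen after the data were seen. The number of changed genes, 2493, stayed within 1.5 times of itself (1752 to 3223) with no background subtraction, Aquantile, an offset of 10, either other filter, the mean of probes, the authors' table, either other moderated model and kept outlier spots. The median spread of dim genes between arrays was 0.14 in the main setting and 0.177 with no background subtraction. It was 0.228 with an offset of 10 and 0.379 with processed signals. For bright genes the spread was 0.159 to 0.174 over these settings. The processed signals are also corrected for dye, so the part of background was not separated. Leaving out an array gave 596 to 3694 changed genes, 202 to 1310 higher and 394 to 2384 lower, with the lowest counts without replicate 3. It gave 23 to 42 genes changed at least 2-fold and 13 to 18 lists. The gene sets tested then differed too, since detection was judged on the arrays left.

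With the scanner's processed signals 3 genes changed, 2 higher and 1 lower (among them A_19_P00327060 and RASD1, chosen after their values were seen), 3 at least 2-fold, and 2789 had an unadjusted p under 0.05. The median spread of dim genes between arrays was then 0.379 against 0.14, and prior degrees of freedom were 3.71 against 14.6. With trend and robust moderation together the same signals gave 1260 changed genes, 582 higher and 678 lower, with 131 at least 2-fold, and the cause was not tested. Processed signals gave correlations of 0.205 for arrays 1 and 2 and 0.421 for arrays 1 and 3. An offset of 10 gave 56 genes changed at least 2-fold, no filter gave 1382 higher genes, and the authors' table gave 1004 lower genes, and the cause was not tested. The test against 1.5-fold left 7 genes, since it asks for a larger change. None of the lists passed with fry (0) or with an estimated correlation (0).

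Median centring in place of loess moved the median of all genes to -0.535 and gave 9709 changed genes, 24 higher and 9685 lower, with 1451 at least 2-fold and a correlation of 0.692 between arrays 1 and 2. The median was then -0.268 for dim and -0.832 for bright genes, a trend for which dye and sample are not separated. Centred over the genes tested, it gave 5551 changed genes, 2545 higher and 3006 lower, with 90 at least 2-fold. Relative to other genes 5 lists reversed under both centrings, to -0.0151 for endoplasmic reticulum chaperones, -0.0209 for glutathione metabolism, -0.0437 for proteasome subunits, -0.0272 for glycolysis and -0.198 for the respiratory chain. Centred over the genes tested, ARHGEF15 (0.0886), UBE2DNL (0.155) and FTH1 (-0.0763) reversed. Centred over all spots, 25 named genes that had risen lay below 0, all but FTH1 of them above that median, with SDF2L1 at -0.141, PDIA4 at -0.258, SEC61B at -0.448, FTH1 at -0.611, MGST1 at -0.274, GSS at -0.297, GPX3 at -0.00424, PSMC2 at -0.0851, PSMD11 at -0.188, PSMD8 at -0.369, PGAM1 at -0.358, LDHA at -0.532, PFKP at -0.523, ATP5MC3 at -0.489, NDUFB3 at -0.439, ATP5MC1 at -0.446, MCM7 at -0.257, MCM2 at -0.102, CDKN3 at -0.15, CTSD at -0.191, NEU1 at -0.268, TFRC at -0.0259, KRT8 at -0.259, ISG15 at -0.256 and DEGS1 at -0.095.

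Over 82 named genes and these settings, 1175 of 1390 values kept their direction and their side of the threshold, 187 kept the direction alone and 28 reversed, and none of these genes kept its call in all. For the 14 lists these numbers were 216 of 266, 40 and 10. The lists of replication, mitosis, ATF4 targets, interferon response and immediate early genes passed under each alternative except fry and the estimated correlation.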

Other observations

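Tests on other probes, brightness of arrays 1 and 3, exchanged dye labels and stress of the endoplasmic reticulum were chosen after results were seen. The other tests here were chosen before their own outcomes were seen. Those on base composition, array 1 and the ribosomal proteins address patterns found in these same data.

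Array 1 lay below the others in lists of amino acid supply, a difference that was not tested. The mean log2 ratio of the aminoacyl-tRNA synthetases was -0.457 on array 1 against 0.133 and 0.0997, and that of serine and amino acid supply -0.59 against -0.209 and -0.0947. SLC7A11 was at -1.93 on array 1 and -0.203 and -0.797 on the others. The unnamed feature A_19_P00327060, chosen after its value was seen, was well above background in the extract channel on 3 of 3 arrays and in the vehicle channel on none, so its fold is not given. Among the polyamine genes MAT2A, likewise chosen after its value was seen, had a log2 ratio of 0.879.

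Genes of replication and mitosis were higher and ATF4 targets lower with an extract given at a concentration that inhibits proliferation. Corrected for base counts and brightness of the probes, the gap between these groups was 1.1 ± 0.173 over 3 arrays, against 1.09 ± 0.154 before. This argues against base composition as the whole source. That correction explained only 6.36%, 5.55% and 3.82% of the variance on arrays 1, 2 and 3, and covers no other property of a probe. Dye bias of single probes stays open. In all 12 genes with another probe at a separate place the median of such probes had the sign of the list. Of all tested genes with such a probe, 1297 of 1979 agreed in sign with their main probe. The exact binomial test against equal signs (p = 0.000488, two-sided) treats members of a list as independent, so nothing is concluded from it. Only 12 of 88 members have such a probe, and those of the ATF4 targets had a median of -0.21 where the main probes had -0.94. Dye labels exchanged on all arrays would turn every direction and cannot be told apart from the labelled design, since the authors' table runs as labelled on 3 of 3 arrays but rests on the same labels, and an effect of the extract itself is equally untested.

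The lower agreement of array 1 was weighed against its weaker green signal and against the position of spots within the array. Among the 4264 brightest genes the correlation of arrays 1 and 2 was still 0.293 below that of arrays 2 and 3, which argues against weak signal as the whole source of that gap. For arrays 1 and 3 the gap was 0.0892, against 0.112 over all genes, and weak signal stays open there. Each array's departure correlated with that of neighbouring spots at 0.0845 for array 1, 0.0902 for array 2 and 0.147 for array 3. The low value of array 1 argues against position within the array. The place of the arrays on the slide was not tested. A difference between the cultures themselves was not tested.

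The fall of the ribosomal protein genes may reflect normalization of the brightest probes. Their mean lay at percentile 0.07 of 10000 random lists of the same brightness, but those lists share the loess curve, so that test cannot exclude it. The shift of the list relative to other genes was -0.0709 in the authors' table, -0.0241 with the scanner's processed signals and -0.799 with median centring, so its size cannot be told apart from the choice of normalization.

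A hypothesis of lower stress of the endoplasmic reticulum as a whole would have its chaperones fall with the ATF4 targets. Their mean log2 ratio was 0.121 ± 0.0348 over 3 arrays, but the direction relative to other genes reversed with median centring, so the hypothesis stays open.

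Turning the sign of some arrays gives 4 distinct patterns, too few for a share under 0.05. The real pattern gave 2493 changed genes and the highest of the others 0, and 1 of the 4 patterns gave as many genes. For the gene lists the real pattern gave 14 and the highest of the others 11, with array 1 exchanged, against 8 with array 2 and 10 with array 3 exchanged. Each of these other patterns leaves 2 arrays with their real sign, so its counts do not stand for an absence of effect.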
